A study of Naumovozyma castellii and Nakaseomyces glabratus and Kluyveromyces lactis with 103 samples.

How the data were processed

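The data are 2-colour Agilent expression arrays of 6 yeasts in a KCl time course. Per the labels' protocols, cells grew in a rich medium at 30 °C (25 °C for N. castellii) to mid-log density and were mixed with medium with or without KCl. Per the labels, the sample was labelled with Cy5 (red) and a reference pool with Cy3 (green) on every array, with no dye swap. Of the 103 samples, 102 had a scanner file, and the S. cerevisiae 0.8 M 20 min sample was read only from the value table. The arrays lay on 16 slides, 4 for S. cerevisiae, 4 for N. castellii and 2 for each other species.

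Per the file headers, the authors' scanner files came from Agilent Feature Extraction 10.1.1.1 for S. cerevisiae and 10.5.1.1 for the other species, and the submitters' processing notes name 10.5.1.1. The deposited intensity values are each spot's mean red and green brightness with the median of its local background, and the processed intensity values had been background-subtracted and dye-normalized by the scanner software, per the file headers. The deposited log10 values of the same files are the log10 of red over green processed signal. The deposited value tables hold log10 of sample over pool in the same direction. Their column medians ran from -0.00913 to 0.0279, and no further centring was found. How spots were combined is not given in the sources used here. Matched by probe name or order of first appearance, the table values correlated with the scanner log ratios at r = 0.967 to 1.00 in 5 species. In S. pombe only the sorted values could be set against the arrays (lowest r = 0.99989), so its table names no gene.

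Background was corrected with normexp (offset 50), control spots had weight 0 in the within-array loess, and spots the software marked as outliers were left out. A probe was kept if it was well above background in either channel on at least 50% of the arrays of its species. Spots of a probe and then probes of a gene were averaged. Repeat arrays of the same dose and time were averaged, because the labels do not say that they are separate cultures. No probe was saturated in the red channel of any array. The software was R 4.3.3, limma 3.58.1, matplotlib 3.10.9 and the data.table package 1.17.8.

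Samples were grouped by species, dose and time from their titles, and for 4 arrays (3 of S. cerevisiae and 1 of N. castellii) the source name gave another dose or time. The array with Pi in its title was left out of all groups. For each species limma fitted the log2 ratios to time as 5 levels and, within each KCl time, a slope on log2 of KCl over 0.4 M, with the 3 T0 samples as 1 group. The tests were an F test over the 4 times, the mean of the 4 time effects (the mean KCl response), an F test over the 4 slopes, and the slope at 80 min minus that at 10 min. Variances were moderated with an intensity trend, and Benjamini-Hochberg adjustment used a threshold of 0.05. The second fit, added after the data were seen, took each dose and time point against the T0 group and 0.8 M against 0.2 M at each time, with the spread from the 3 T0 samples (2 degrees of freedom). In N. castellii the numbered arrays at 0.8 M were tested across 0, 10, 20 and 80 min.

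Gene lists were written before the data were examined, and a list needed 5 measured members. Of 18 lists, 17 could be tested in S. cerevisiae, the hyphal list being for C. albicans only, and 1 in S. pombe through systematic names in the list. They were tested on the mean KCl response with camera (preset correlation 0.01), with an estimated correlation, and with fry. Members were counted over all genes and adjusted over the list alone. The rule for named genes took, among genes past the threshold with 1 sign at every point, those with the largest mean rise and fall, and allowed any list member, with GPD1, RHR2, HOR2, STL1, CTT1, HSP12, TPS1 and TPS2 first. Where the files pair no identifiers with names, at most 2 identifiers up and 2 down are given. The annotation table provided is of N. castellii and held none of the identifiers of its arrays, so it named no gene.

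The time, mean KCl and dose tests, the single-point test and that of 0.8 M against 0.2 M at 10 min were run on simulated data for each species. In each, 200 genes had a known change, in independent noise of the observed spread. The change was equal at all KCl points, linear in log2 dose, or confined to 1 point. Changes that come and go over several points or are shared between genes were not simulated, nor were the list tests, the slope difference or the repeat arrays. For a log2 change of 2 the share recovered in S. cerevisiae, with the residual spread of the fit over 5867 genes, was 86.5% for the time response and 42.5% for 0.8 M against 0.2 M at 10 min. In N. castellii over 5553 genes that dose difference recovered 0% with the residual spread and 73.5% with the T0 spread. The single-point test recovered 0% in N. castellii and C. albicans with the residual spread, and 85.5% and 82.5% with the T0 spread. For a log2 change of 1 both tests recovered 0% in S. cerevisiae, N. castellii and C. albicans with either spread.

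Alternatives set beforehand were the scanner's processed log ratios, median centring, Aquantile, 2 probe filters, the value table, own-series T0 blocks, repeat arrays kept separate, slide blocks, the median of probes, no intensity trend, arrays with conflicting labels left out, other dose terms, single slides, N. castellii, whose slides were scanned on 3 dates, without the slide of the first, and leaving out each point in turn. Added later were the point-by-point fit and a fit without the 0.8 M samples. Median centring, where loess does not level high and low intensities, shifted the median of all genes by -0.144 to 0.110 (log2) in S. cerevisiae and by -0.121 to 0.0586 in N. glabratus. The comparison between species was not run, because fewer than 500 genes share a name. Arrays of 1 species and 1 dye orientation correlated down to -0.741 between conditions, and the stated dyes were kept.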

Results

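The arrays measured messenger RNA in 6 ascomycete yeasts moved from rich medium into the same medium with KCl, a salt that raises the osmotic strength outside the cell. The species were the budding yeasts Saccharomyces cerevisiae, Nakaseomyces glabratus, Naumovozyma castellii and Kluyveromyces lactis, the opportunistic pathogen Candida albicans, and the fission yeast Schizosaccharomyces pombe. Each species had a KCl series at 0.2, 0.4 and 0.8 M, sampled at 10, 20, 40 and 80 min, and each series had its own T0 sample from control medium without KCl. The 103 samples fell into 79 groups, with 15 samples of S. cerevisiae, 24 of N. castellii and 16 of each other species. Most dose and time points had 1 array, and the T0 samples of the 3 series formed 1 group of 3 per species. Each array set the sample against a reference pool, and values are log2 ratios of sample over pool as labelled. In S. pombe the channel labelled as the pool behaved like a sample, as set out below. Between 81.9% and 98.6% of probes (both ends in N. glabratus) were well above background in the sample channel of an array in the 5 budding yeasts. In S. pombe the share was 96.1% to 99.4% in the channel labelled as the sample (Cy5) and 91.6% to 96.4% in the other. In all, 4980 to 5867 genes per species were tested. Nothing in the labels says that repeat arrays came from separate cultures, so the p-values measure the spread between these samples, which can be technical. In the model fixed beforehand that spread also holds the departure of the 3 doses from a line on the log2 dose scale. The number of arrays limits the precision.

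The first question, from the labels, was how each transcriptome moved over 80 min of KCl at each dose. After loess, the change against T0 was larger at 0.2 and 0.4 M than at 0.8 M after 10 min in all 6 species. The root mean square (RMS) log2 change over all genes of S. cerevisiae at 10 min was 0.903 at 0.2 M, 0.808 at 0.4 M and 0.218 at 0.8 M, while at 40 min it was 0.335, 0.452 and 1.15. Under median centring the 10 min change of this species at 0.8 M was 1.02 times that at 0.2 M, against 0.242 times after loess, and the ratio stayed at or below 0.436 in the other 5 species. At 20 min in 0.8 M the RMS had reached 0.815 in N. glabratus and 0.747 in C. albicans, above 0.693 and 0.674 at 0.2 M, but stood at 0.223 in K. lactis, 0.270 in N. castellii and 0.267 in S. pombe. The 0.8 M series was highest at 40 min in S. cerevisiae, N. glabratus (1.01) and C. albicans (0.960), and at 80 min in N. castellii (1.23), K. lactis (1.04) and S. pombe (0.892). At 80 min in 0.2 M the RMS was 0.237 in S. cerevisiae and 0.248 in N. castellii, where the lowest T0 samples stood at 0.270 and 0.257. That S. cerevisiae array, like the one titled 0.4 M and 40 min, has a source name that gives another dose or time. Each T0 sample was set against the mean of the other T0 samples and each KCl point against the mean of all. This alone makes T0 values somewhat larger, so the small gap in N. castellii is not a difference. The RMS at that point was 0.302 in N. glabratus, 0.329 in C. albicans, 0.353 in K. lactis and 0.356 in S. pombe, above their T0 samples, which reached 0.289, 0.322, 0.297 and 0.217.

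**Figure D1:**
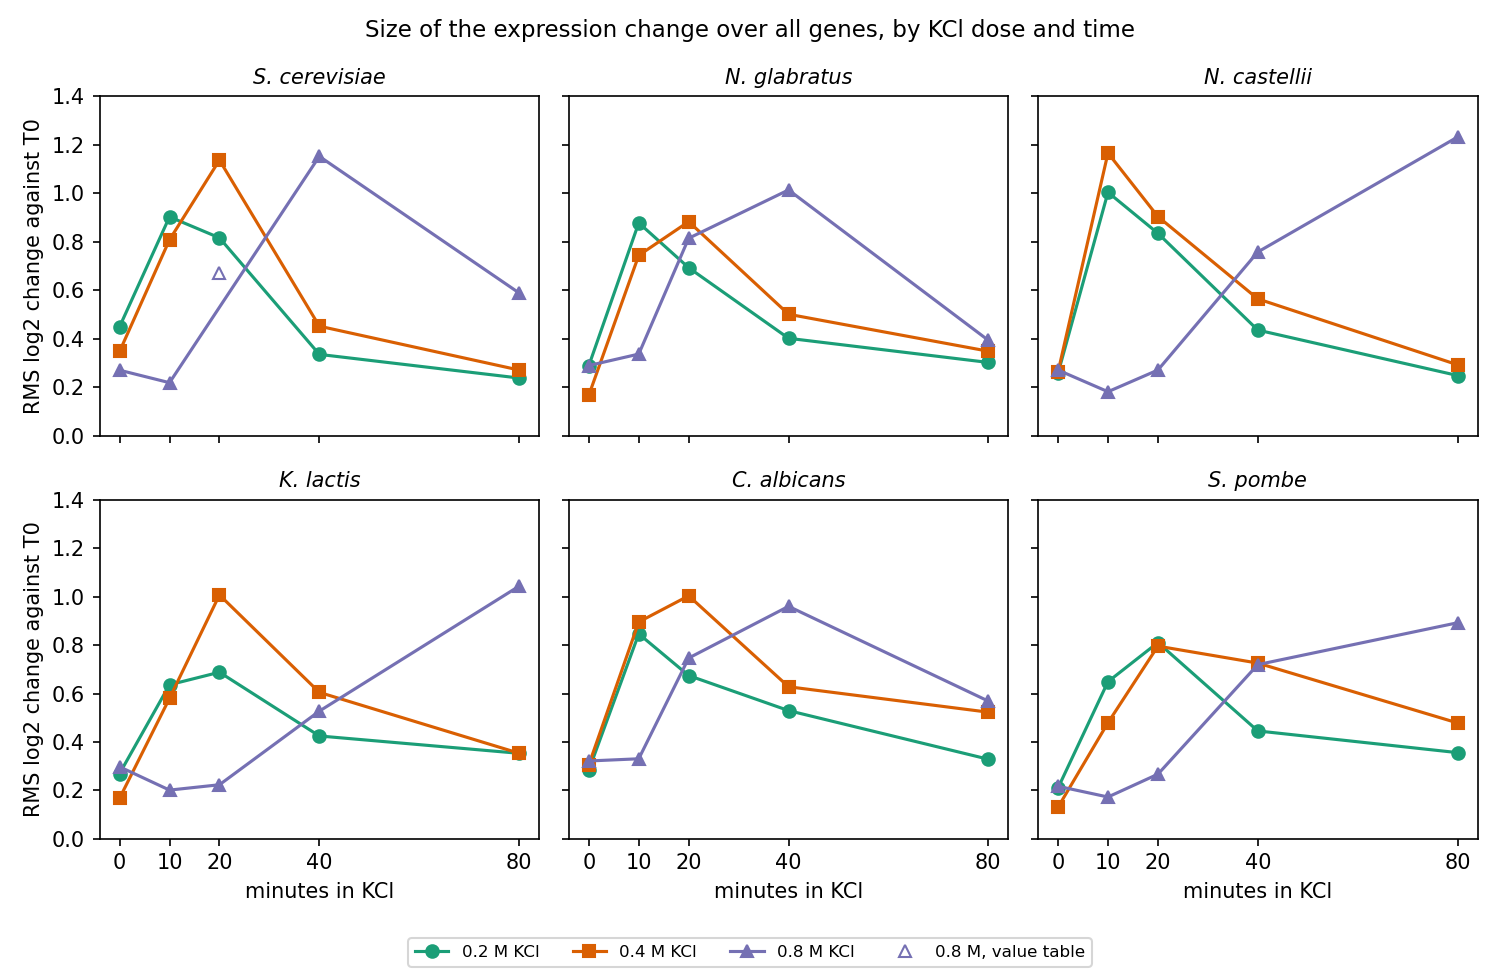
Root mean square log2 change over all tested genes against the mean of the T0 samples (vertical axis) by minutes in KCl (horizontal axis), 1 panel per species and 1 line per KCl dose, with repeat arrays averaged and points at 0 min showing each T0 sample against the mean of the other T0 samples. The open triangle is the S. cerevisiae 0.8 M 20 min array, read from the deposited value table (0.670); the 0.8 M lines lie at 0.173 to 0.336 at 10 min.

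The model fixed before the data were examined gave each time its own mean and its own slope on the log2 dose scale. By its F test over the 4 times, 1270 genes of N. glabratus, 837 of S. pombe and 222 of C. albicans changed with time in KCl. In S. cerevisiae the only gene past the threshold was YDR492W, named here after its value was seen (mean KCl response -0.88 ± 0.09 SE). limma called 0 genes in N. castellii and 0 in K. lactis, where 440 and 336 had an unadjusted p under 0.05, against 1847 in S. cerevisiae. Without the 0.8 M samples after T0 and with time alone, a setting added later, the time count was 3636 in S. cerevisiae, 2838 in N. castellii and 1282 in K. lactis. The mean over the 4 times rose in 358 and fell in 300 genes of N. glabratus and rose in 33 and fell in 56 of C. albicans. limma called 0 genes for that mean in S. cerevisiae, N. castellii and K. lactis, with 1878, 872 and 690 at an unadjusted p under 0.05. In S. cerevisiae that 0 depended on the scaling and on single arrays, with 1088 genes under median centring (and 686 for time), 874 with the scanner's processed log ratios and 1652 without the 0.4 M 40 min array. The median residual SD of this model was 0.197 in S. cerevisiae and 0.279 in N. castellii, against 0.135 and 0.151 between T0 samples. That residual also holds any departure of the doses from a line on the log2 scale, so it is not only a spread between samples. Single arrays decided these counts. Without the 0.4 M T0 sample the time count was 348 in N. glabratus, 5 in C. albicans and 54 in S. pombe, and without the 0.8 M 40 min array it was 1602 in S. cerevisiae. Without that T0 sample the count for the mean was 4 in N. glabratus and 1 in C. albicans. In S. cerevisiae the time count was 1062 without the 3 arrays whose source names give another dose or time than their titles (0.2 M at 80 min, 0.4 M at 40 and 80 min), where 2092 genes changed in the mean. With the own T0 of each series as a block the time count was 325 in N. glabratus, 6 in C. albicans and 75 in S. pombe, and the count for the mean was 182 in N. glabratus and 23 in C. albicans. With repeat arrays kept separate the time count of the 3 species was 1867, 607 and 1782, and with the slide as a block in addition 1937, 405 and 939. In N. castellii the same 2 settings gave 2616 and 1524 genes for time and 1175 and 2121 for the mean, in place of 0, and the first gave 1 for time in K. lactis. Both settings treat repeat arrays as separate samples, which the labels do not state.

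A second fit, added after the data were seen, set each dose and time point against the T0 group, with the spread taken from the 3 T0 samples and a lone array assumed to vary like them. In S. cerevisiae 155 genes rose and 522 fell at 0.2 M and 10 min, 821 rose and 1341 fell at 0.4 M and 20 min, and 1306 rose and 1472 fell at 0.8 M and 40 min. On simulated data a single-point test recovered 0% of log2 changes of 1 in S. cerevisiae and N. castellii. A count of 0 there does not exclude changes of that size. limma called 0 genes at 0.8 M and 10 min in S. cerevisiae, N. castellii, K. lactis and S. pombe, where 38, 12, 27 and 242 had an unadjusted p under 0.05, against 8 in N. glabratus and 6 in C. albicans. At 0.8 M and 80 min the number was 3144 in N. castellii, 2990 in K. lactis and 2928 in S. pombe, but 98 in S. cerevisiae, 44 in N. glabratus and 295 in C. albicans. Over all points together 854 genes of S. cerevisiae changed. Without the T0 sample of the 0.8 M series this count was 122 and those at the 3 points named were 106, 903 and 1101, and without that of the 0.2 M series they were 1729, 1838, 2856 and 3180. Without the T0 sample of the 0.2, 0.4 or 0.8 M series, in that order, the count at 0.8 M and 80 min was 338, 7 and 3 in S. cerevisiae and 324, 0 and 256 in N. glabratus (475 in C. albicans without the last of these), and at 10 min it was 137, 0 and 39 in N. glabratus and 16, 0 and 15 in C. albicans. Where limma called 0 in these fits 425 (N. glabratus at 80 min), 251 (N. glabratus at 10 min) and 397 genes (C. albicans) had an unadjusted p under 0.05. In K. lactis and S. pombe 1 and 8 genes passed at 0.8 M and 10 min without the T0 sample of the 0.8 M series.

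Several genes of glycerol synthesis and of the general stress response rose strongly in S. cerevisiae at single points of the second fit, though only part of each list passed at a point. GPD1, the glycerol 3-phosphate dehydrogenase that makes the precursor of the osmolyte glycerol, rose by 6.61 ± 0.31 (log2, SE; adjusted p = 0.0059) at 0.2 M and 10 min, by 6.88 at 0.4 M and 20 min and by 7.34 at 0.8 M and 40 min. HOR2 and RHR2, the glycerol 3-phosphatases of the next step, rose by 6.04 ± 0.32 and 2.27 ± 0.17 at 0.2 M and 10 min and by 6.93 and 3.54 at 0.8 M and 40 min. The glycerol importer STL1 read 7.34 ± 1.80 at 0.2 M and 10 min, which did not pass (adjusted p = 0.067), and rose by 7.45 at 0.8 M and 40 min. Of the 12 measured genes of glycerol metabolism and transport, 4 rose at 0.2 M and 10 min, 6 at 0.4 M and 20 min and 9 at 0.8 M and 40 min.

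The heat shock protein gene HSP12 rose by 7.88 ± 0.92 at 0.2 M and 10 min and by 9.51 at 0.4 M and 20 min, and it still stood 8.67 above T0 at 0.8 M and 80 min (adjusted p = 0.039). CTT1, the cytosolic catalase, rose by 6.65 ± 1.30 at 0.2 M and 10 min and by 7.74 at 0.8 M and 40 min. The chaperone gene HSP104 rose by 2.99 ± 0.31 and the glucokinase gene GLK1 by 3.99 ± 0.36 at 0.2 M and 10 min. Of 38 general stress genes, 15 rose at 0.2 M and 10 min, 24 at 0.4 M and 20 min, 27 at 0.8 M and 40 min and 5 at 0.8 M and 80 min. Among 18 genes of trehalose and glycogen metabolism 11 rose at 0.4 M and 20 min and 11 at 0.8 M and 40 min. They included the trehalose synthesis genes TPS1 (3.48 ± 0.53 at 0.2 M and 10 min) and TPS2 (4.70 ± 0.44). The T0 sample of the 0.2 M series itself stood above the T0 mean for STL1 (2.70), HSP26 (2.61), DDR2 (2.17), CTT1 (1.84) and HSP12 (1.37).

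**Figure D2:**
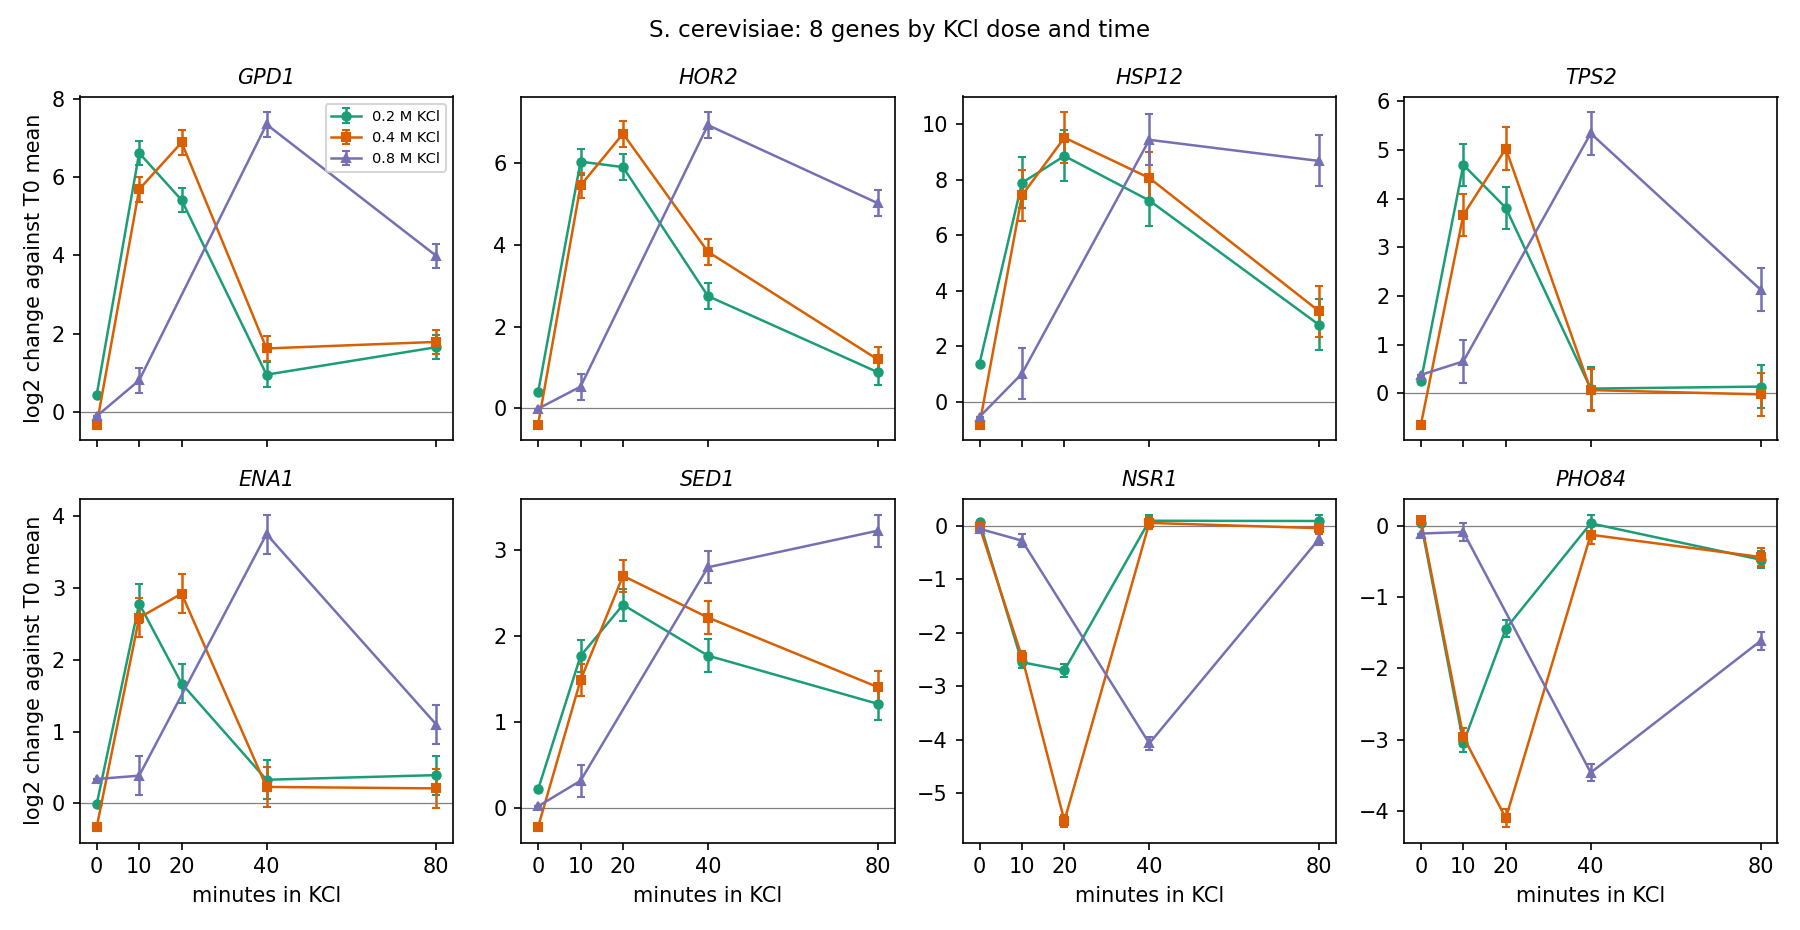
Log2 change against the T0 mean (vertical axis) by minutes in KCl (horizontal axis) for 8 S. cerevisiae genes, 1 line per dose, with the standard error of the second fit as error bars on the KCl points and each T0 sample at 0 min without one. GPD1 stands at 6.61 at 0.2 M and at 0.80 at 0.8 M after 10 min, and NSR1 reaches -5.52 at 0.4 M after 20 min.

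By camera on the mean KCl response, the general stress list (median 2.59, adjusted p = 6.46e-15), trehalose and glycogen metabolism (1.07, 4.59e-06) and glycerol metabolism (1.13, 3.31e-04) rose against other genes. With an estimated correlation their adjusted p were 0.329, 0.389 and 0.329, so none of these calls held. By fry, which tests whether a list moves on balance in its own direction, the adjusted p was 0.0354 for general stress, 0.0892 for trehalose and glycogen and 0.0685 for glycerol. None of their members passed over all genes for the mean KCl response, and 24, 10 and 6 passed upward when adjusted over the list alone. Glycolysis and fermentation (17 genes, median 0.48, adjusted p = 1.38e-06, and adjusted p = 0.329 with an estimated correlation) rose under loess, with the phosphoglycerate kinase gene PGK1 up by 1.31 ± 0.08 at 0.4 M and 20 min, where median centring gave -0.51. Its list median at that point was 0.86 under loess and -0.77 under median centring, so its direction depends on the scaling.

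Smaller rises were called by camera for the proteasome (33 genes, median 0.24, adjusted p = 3.81e-05), the tricarboxylic acid cycle and respiration (40 genes, 0.21, 0.00166) and the cell wall (24 genes, 0.13, 0.0455). Their adjusted p with an estimated correlation were 0.424, 0.424 and 0.414, and by fry 0.190, 0.213 and 0.161. Median centring turned the respiration and cell wall lists and ended the proteasome call (adjusted p = 0.911). At 0.8 M and 40 min the wall mannoprotein genes CWP1 and SED1 rose by 4.40 ± 0.39 and 2.80 ± 0.19, while the glucanase gene EXG1 fell by 1.49 ± 0.16. The list of osmosensing and Hog1 pathway genes did not pass (24 genes, median 0.17, adjusted p = 0.250), nor did cation transport (25 genes, 0.20, 0.0507) or mating and filamentous growth targets (19 genes, -0.11, 0.324) by camera. By fry the mating list fell (adjusted p = 0.0224) and the other 2 did not pass (0.402 and 0.190). Within cation transport the sodium pump gene ENA1 rose by 2.78 ± 0.27 at 0.2 M and 10 min and by 3.75 at 0.8 M and 40 min, and the potassium importer gene TRK1 fell by 0.82 ± 0.14 and by 0.99. HOG1 itself rose by 0.63 ± 0.14 at 0.8 M and 40 min.

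Genes that build ribosomes fell in S. cerevisiae at the same points. NSR1, which encodes a nucleolar protein, fell by 2.55 ± 0.12 at 0.2 M and 10 min, by 5.52 at 0.4 M and 20 min and by 4.07 at 0.8 M and 40 min, and read 0.05 on the array titled 0.4 M and 40 min. UTP4, a component of the small-subunit processome, fell to -2.14 ± 0.14, -3.79 and -3.12 at the 3 points. RPA190, the largest subunit of RNA polymerase I, stood at -0.89 ± 0.15, -3.08 and -2.27, each past the threshold. Of 106 ribosome biogenesis genes, 94 fell at 0.2 M and 10 min, all but 1 at 0.4 M and 20 min, 104 at 0.8 M and 40 min and 1 at 0.8 M and 80 min. The list of cytosolic ribosomal proteins was matched by gene name and also holds RPP1, which encodes a subunit of RNase P. Of its 138 genes, 111 fell and 1 rose at 0.4 M and 20 min, and 110 fell and 2 rose at 0.8 M and 40 min. The high-affinity phosphate importer gene PHO84 fell to -3.04 ± 0.12 at 0.2 M and 10 min and to -4.10 at 0.4 M and 20 min, and 14 of 16 phosphate starvation genes fell at the latter point.

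By camera on the mean KCl response, ribosome biogenesis (median -1.21, adjusted p = 1.68e-30), ribosomal proteins (-0.34, 1.87e-18), RNA polymerase I and III subunits (-0.86, 3.67e-08) and phosphate starvation (-1.18, 3.14e-08) fell against other genes. With an estimated correlation the adjusted p was 0.329 for each of the 4 lists, and 0 of their genes passed limma over all genes, where 1878 genes of any kind had an unadjusted p under 0.05. By fry, which does not set a list against other genes, the adjusted p was 0.0294, 0.0224, 0.0354 and 0.0224 in that order. Adjusted over the list alone, all but 1 of 106 ribosome biogenesis, 94 of 138 ribosomal protein, 18 of 19 polymerase and 14 of 16 phosphate genes fell. Amino acid biosynthesis (64 genes, -0.28, 1.46e-05), ergosterol biosynthesis (27 genes, -0.26, 0.00200) and cyclins with core histones (24 genes, -0.30, 0.00979) also fell by camera, with adjusted p = 0.329, 0.414 and 0.329 with an estimated correlation. Their adjusted p by fry were 0.0224, 0.0767 and 0.0249. The size of the ribosomal protein change depended on the scaling, with a list median at 0.8 M and 40 min of -0.73 under loess and -2.23 under median centring.

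**Figure D3:**
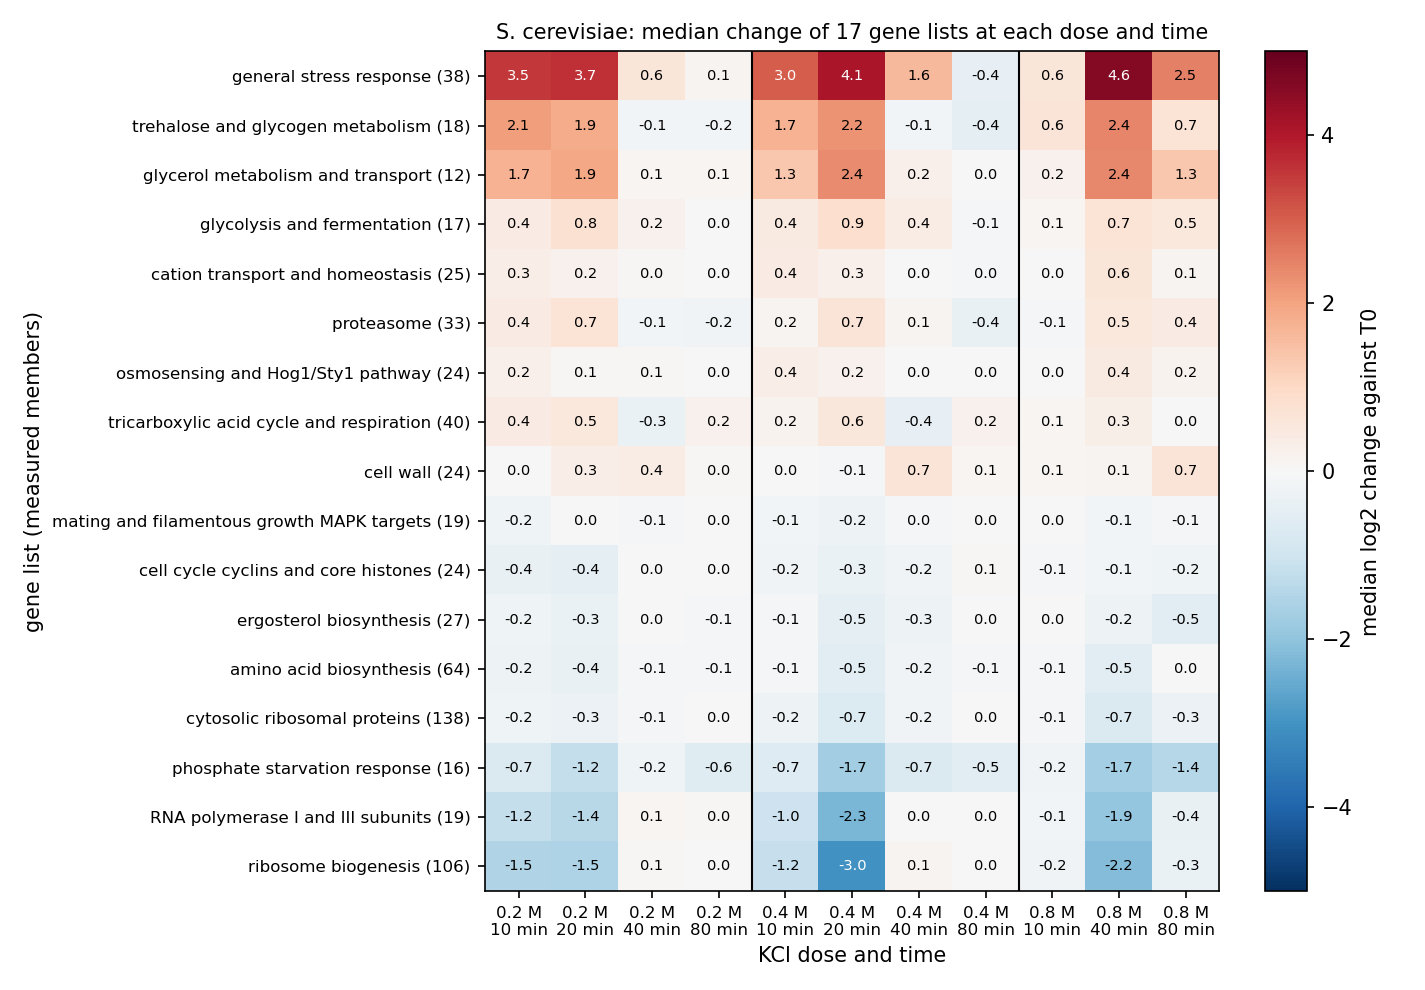
Median log2 change against the T0 mean of 17 S. cerevisiae gene lists fixed before the data were examined (vertical axis, with the number of measured members) at each KCl dose and time (horizontal axis), after loess. Red is above and blue below T0; the general stress list reads 4.60 and ribosome biogenesis -2.17 at 0.8 M and 40 min, and 51 of the 187 cells, 9 of them in the glycolysis list, change sign under median centring or with the scanner's processed log ratios.

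The labels also pose the question of dose. At 10 min induced and repressed genes of S. cerevisiae stood closer to T0 at 0.8 M than at 0.2 M after loess. Under median centring this held for the medians of ribosome biogenesis (-0.70 at 0.8 M, -1.73 at 0.2 M) and general stress (0.42 and 3.51). It did not for ribosomal proteins (-0.90 and -0.92), which were near equal, or for amino acid biosynthesis (-0.70 and -0.52). Nor did it for glycolysis (-0.74 and -0.34), the proteasome (-0.72 and 0.10), respiration (-0.54 and 0.06) or the cell wall (-0.61 and -0.49). Ergosterol (-0.62 and -0.55) and osmosensing (-0.22 and 0.12) also stood farther from T0 at 0.8 M. The remaining lists stood closer, though cation transport (-0.32 and 0.35) barely did. GPD1 was lower at 0.8 M than at 0.2 M (log2 difference -5.81), as were TPS2 (-4.04) and HSP104 (-3.29), while PHO84 (2.95) and NSR1 (2.27) were higher. Each of these doses had 1 array at 10 min in S. cerevisiae. The spread came from the T0 samples alone, so the variation of neither dose was tested, here or in the counts that follow. The median difference of 0.8 M from 0.2 M was 1.32 over the 106 ribosome biogenesis genes and -2.75 over the 38 general stress genes. Both list differences passed camera (adjusted p = 5.78e-43 and 9.50e-11) and neither held with an estimated correlation (adjusted p = 0.451 and 0.484).

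Counted over all genes, 0.8 M differed from 0.2 M at 10 min in 188 genes of S. cerevisiae (163 higher and 25 lower), 1738 of N. glabratus, 1917 of N. castellii, 433 of K. lactis, 978 of C. albicans and 1118 of S. pombe. At 40 min, again with 1 array per dose, the difference in S. cerevisiae ran the other way for GPD1 (6.40) and NSR1 (-4.16). The 10 min count in S. cerevisiae was 0 by limma without the T0 sample of the 0.8 M series (1038 at an unadjusted p under 0.05) and 1283 under median centring (1139 higher and 144 lower), and the scanner's processed log ratios gave a nearly even split (741 higher and 709 lower). In K. lactis these 2 scalings gave 2332 and 1356. The count was 494 in N. glabratus and 17 in K. lactis without the T0 sample of the 0.4 M series. With repeat arrays kept separate it was 2037 in N. glabratus, 1255 in K. lactis, 1653 in C. albicans, 1550 in S. pombe and 3697 in N. castellii, and with the slide as a block in addition 1092, 542, 784, 1133 and 3417. In the model fixed beforehand, the F test of the 4 dose slopes called 3 genes in N. glabratus, 1 in C. albicans (orf19.4450.1, slope -1.47 ± 0.13 per doubling of KCl at 80 min) and 0 by limma in the other 4 species, where 1053 (S. cerevisiae), 877 (N. castellii), 4.18% of 5138 genes (K. lactis) and 1539 (S. pombe) had an unadjusted p under 0.05. These counts depended on the dose scale. On a linear scale they were 818 in S. cerevisiae, 1713 in N. glabratus, 5 in C. albicans and 1173 in S. pombe, with no such move in N. castellii and K. lactis. With repeat arrays kept separate the count in N. castellii was 4220.

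The early change at 0.2 M was set against the 0.8 M series. Across 5867 genes of S. cerevisiae, each series taken against its own T0 so that no control was shared, the change at 0.2 M and 10 min correlated with that at 0.8 M at r = 0.455 at 10 min, 0.828 at 40 min and 0.459 at 80 min (Spearman 0.449, 0.784 and 0.355). In N. castellii the r was 0.751 at 80 min (Spearman 0.736). These are correlations across genes, which are not independent replicates. The S. cerevisiae array at 0.8 M and 20 min, present only in the deposited value table, read GPD1 at 3.92, HSP12 at 6.17 and CTT1 at 5.51 against the T0 samples of that table, with 477 genes over 2-fold.

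Outside S. cerevisiae the files pair no identifiers with gene names, so only identifiers are given. In N. glabratus CAGL0M11660g and CAGL0K09702g had the largest mean rise (4.33 ± 0.38 and 3.99 ± 0.37) and CAGL0B04433g and CAGL0D05940g the largest mean fall (-1.70 ± 0.28 and -1.67 ± 0.22) among genes past the threshold with 1 sign at every point, which numbered 152 up and 165 down. In C. albicans orf19.3548.1 and orf19.5753 rose (5.96 ± 0.65 and 4.01 ± 0.51) and orf19.1691 and orf19.5674 fell (-4.32 ± 0.62 and -3.07 ± 0.47), among 18 up and 38 down. The largest single-point counts were 1259 up and 1393 down for N. glabratus at 0.8 M and 40 min (1585 in all without the 0.4 M T0 sample), 998 up and 1112 down for C. albicans at 0.4 M and 20 min, and 1514 up and 1476 down for K. lactis and 1647 up and 1497 down for N. castellii at 0.8 M and 80 min. Whether a response differed between species was not tested, because fewer than 500 genes share a name.

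N. castellii at 0.8 M was the only series with numbered repeat arrays at 0, 10, 20 and 80 min. Between the 4 times 4758 of 5564 genes changed, and 4841 with the slide, which parts arrays 1 and 2, as a block. The change against 0 min grew from an RMS of 0.121 at 10 min, where limma called 0 genes and 537 had an unadjusted p under 0.05, to 0.242 at 20 min (536 up and 412 down) and 1.26 at 80 min (2352 up and 2207 down). The 2 arrays of a time correlated across genes at r = 0.957 to 0.981. The labels do not say that they are separate cultures. If they are repeat arrays of 1 culture, these p-values measure array noise and the counts do not extend to other cultures.

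For S. pombe the direction of every value is as labelled, with the sample in Cy5, and would have the opposite sign if the dyes had been exchanged. As labelled, SPBC16E9.16c and SPBC21C3.19 fell most (-5.41 ± 0.69 and -4.32 ± 0.51) and SPCC1393.10 and SPAC8E11.10 rose most (2.13 ± 0.36 and 1.67 ± 0.27), within 557 genes up and 828 down for the mean KCl response. These 1385 genes were 14 without the 0.4 M T0 sample and 379 with the own T0 of each series as a block. The 5 measured general stress genes all fell as labelled (median -2.30, camera adjusted p = 8.17e-05, adjusted p = 0.0753 with an estimated correlation and 3.52e-04 by fry), and all 5 passed over all genes and adjusted over the list alone. Taken 1 channel at a time, their median log2 change from T0 to KCl was -0.0300 in Cy5 and 2.01 in Cy3. The dose slope at 80 min differed from that at 10 min in 696 genes, 284 upward and 412 downward as labelled. At an unadjusted p under 0.05 there were 1850 of 4980 genes, against 1994 of 5553 in N. castellii, where limma called 0. Across arrays the Cy5 channel of S. pombe varied less than the Cy3 channel (ratio of median gene SDs 0.723), whereas in the other 5 species Cy5 varied more (1.62 to 2.27). Arrays of 1 species reached correlations as low as -0.581 (C. albicans) to -0.741 (N. castellii) between conditions, with the dyes stated in the labels.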

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

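Tests chosen after the result was seen were those of 0.8 M against 0.2 M, those of loess in the other 5 species and among genes of like intensity, the slide tests of N. castellii and of the T0 samples, the counting of any 0.8 M array in the test of weak signal, the test of the stress genes in the Cy5 channel of S. pombe, and all regroupings of the samples.

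The response at 10 min was smaller at 0.8 M than at 0.2 M after loess, and the test of the difference called 188 genes in S. cerevisiae, 1738 in N. glabratus, 1917 in N. castellii, 433 in K. lactis, 978 in C. albicans and 1118 in S. pombe. A slide effect is excluded in N. glabratus, K. lactis, C. albicans and S. pombe, where the repeat of the 0.4 M 20 min array on the slide of the 0.8 M series gave at least 0.864 times the RMS change of its partner. It is also excluded in N. castellii, where the 0.8 M 80 min arrays on the slides of the 10 min arrays changed from the T0 array of their slide by at least 1.41 times the RMS change at 0.2 M and 10 min. It stays open in S. cerevisiae, where the slide of the 10 min array is not known to hold a later array of the 0.8 M series. A low share of probes above background is excluded as a common cause, since a 0.8 M 10 min array had the lowest share on its slide in 1 of 6 species (1 of 2 N. castellii arrays, at 92.5%). With Cy3 read as the sample in S. pombe it was 2 of 6, the S. pombe array standing at 92.7% against 92.9% for the next. That share does not measure brightness. The median Cy5 brightness of the 0.8 M 10 min array was the lowest of its species in S. cerevisiae (1228.5) and C. albicans (910.4), so weak signal stays open in these 2. In each other species another array was dimmer. Loess is excluded in the other 5 species, where the ratio of RMS change at 0.8 M over 0.2 M reached at most 0.436 under median centring, but stays open in S. cerevisiae, where that ratio went from 0.242 to 1.02, the slope across genes was 0.537 and 91.5% of the variance of the array then lay along intensity, although the median slope among genes of like intensity was 0.278. A slower start of transcription at the highest dose remains a hypothesis, and a wrong time label was not tested.

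The T0 sample of the 0.2 M series leaned toward the KCl response, less clearly in K. lactis. Its difference from the T0 sample of the 0.4 M series correlated across genes with the 0.8 M response, a series that shares neither array, at r = 0.822 in S. cerevisiae, 0.586 in N. glabratus, 0.742 in N. castellii, 0.519 in K. lactis, 0.218 in C. albicans and 0.633 in S. pombe. Its difference from the 0.8 M T0 sample correlated with the 0.4 M response at 0.605, 0.423, 0.496, 0.204, 0.329 and 0.373 in that order. This was weaker in all species but C. albicans, with a Spearman value of 0.0392 in K. lactis. The 0.4 M T0 sample minus that of 0.8 M correlated with the 0.2 M response at -0.252 in K. lactis (Spearman -0.308). It stood at -0.347 in S. cerevisiae and between -0.145 and 0.0796 in the others. In K. lactis a lean of the 0.2 M sample is therefore not told apart from an opposite lean of the 0.4 M sample. A slide effect is excluded in the 5 species other than S. cerevisiae, as the 0.4 M T0 array of the same slide, set against the 0.8 M T0 array, correlated with the 0.2 M response over 0.2 in 0 of 5, but stays open in S. cerevisiae, whose T0 arrays lie on 3 slides. Intensity-dependent dye bias is also excluded, with a median r of 0.634 within bins of genes of like intensity, although C. albicans stood at 0.249. Stress from handling before sampling could produce such a lean, but the design holds no group that tests it, so no biological explanation was tested.

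In S. pombe the general stress genes fell as labelled, and the direction of all genes rests on the dyes in the labels. Dyes exchanged against the labels would account for this, since the channel labelled Cy5 varied less between arrays than the one labelled Cy3 (ratio of median gene SDs 0.723), as a pool would. Noise in the Cy3 channel is excluded, because its changes from T0 to 10 min at 0.2 M and 0.4 M correlated at r = 0.761, against 0.00863 in the Cy5 channel and 0.0352 in the Cy3 channel of S. cerevisiae. A true fall in a Cy5 sample is excluded too, as the median change of the 5 stress genes from T0 to KCl was -0.0300 (log2) in the Cy5 channel alone and 2.01 in the Cy3 channel.

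The slope on dose differed between 80 and 10 min in 2 genes of C. albicans and 696 of S. pombe, by limma. It called 0 genes in N. castellii, K. lactis, S. cerevisiae and N. glabratus, where 1994, 944, 767 and 600 had an unadjusted p under 0.05. That number was 1850 in S. pombe and 288 in C. albicans, so before adjustment N. castellii stood close to S. pombe.

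Dose and time labels were drawn anew 100 times, the real labels included, with doses permuted within each time for the dose response. With labels drawn over all points, under 0.05 of the draws were as large for the time response of N. glabratus (1270 genes, highest other draw 538, 1 draw as large), C. albicans (222, 664, 2 draws) and S. pombe (837, 787, 1 draw). The same held for the mean KCl response of N. glabratus (658, 1317, 2 draws), C. albicans (89, 2, 1 draw) and S. pombe (1385, 1008, 1 draw). These draws ignore that samples came in series, so on their own they do not exclude chance. With the series as a block and times drawn anew within each, the share was also under 0.05 for time in C. albicans (6 genes, highest other draw 1171, 4 draws as large) and for mean KCl in S. pombe (379, 1216, 4 draws). With 5 draws the limit would not have been met, and no correction was made over the results tested, so chance is not firmly excluded there either. It is not excluded, with the series as a block, for time in N. glabratus (325, 2417, 5 draws) and S. pombe (75, 1327, 6 draws) or for mean KCl in N. glabratus (182, 1872, 5 draws) and C. albicans (23, 1400, 5 draws). Without the 0.4 M T0 sample the time count of C. albicans was 5. With the labels drawn over all points, chance is not excluded for time in S. cerevisiae (1 gene, highest other 2422, 7 draws as large) or, with doses drawn within each time, for dose in N. glabratus (3, 242, 10 draws) and C. albicans (1, 10, 5 draws). Where limma called 0 genes all 100 draws were as large by construction, so the draws decide nothing there. For those results 2 unlike numbers are given. The first counts genes at an unadjusted p under 0.05 with the real labels, the second is the highest adjusted count of another draw. The real adjusted count was 0 in each, so the 2 numbers cannot be set against each other. Those results were mean KCl (1878, 2530) and dose (1053, 0) in S. cerevisiae and dose in S. pombe (1539, 698). In N. castellii they were time (440, 1646), mean KCl (872, 2132) and dose (877, 2922), and in K. lactis time (336, 1707), mean KCl (690, 1856) and dose (4.18% of 5138 genes, 2004). Draws with several times the real count point to a structure of the samples, whose nature was not tested.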

How the results depend on the processing

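Tests chosen after the data were seen were the point-by-point fit, its comparison of 0.8 M with 0.2 M and the fit without the 0.8 M samples. As reported, limma called 1, 1270, 0, 0, 222 and 837 genes for time in S. cerevisiae, N. glabratus, N. castellii, K. lactis, C. albicans and S. pombe, in that order. The mean KCl response had 0, 658, 0, 0, 89 and 1385 and the dose response 0, 3, 0, 0, 1 and 0. Genes at an unadjusted p under 0.05, called unadjusted from here on, numbered up to 1878 (mean KCl, S. cerevisiae) where these counts were 0, and stand beside each 0 in the report. For 0.8 M against 0.2 M at 10 min the counts were 188, 1738, 1917, 433, 978 and 1118, and for any point 854, 2623, 3069, 2186, 2223 and 2769. The counts given next moved by over 1.5 times and the lists crossed the threshold or turned. The cause was not tested. Single points gave 759 further counts under other settings, of which 545 stayed within 1.5 times and 214 moved. At least 81.9% of probes on an array were well above background in the sample channel, and the filters on dim probes moved the dose count of N. glabratus and the cation transport list only. The median of probes moved no count by over 1.5 times. Aquantile could move none, because it alters only average intensities and the fit kept those from loess, so it tested nothing here. N. castellii without the slide of its first scan date kept 0 genes by limma for time, mean KCl and dose (437, 859 and 865 unadjusted). The species comparison was not run, and in S. cerevisiae the point-by-point model with a slide block could not be fitted.

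With the scanner's processed log ratios, S. cerevisiae had 2 for time, 874 for mean KCl, 1450 for 0.8 M against 0.2 M at 10 min and 2710 for any point. N. glabratus had 0 (1841 unadjusted) for dose. K. lactis had 1356 for 0.8 M against 0.2 M at 10 min. C. albicans had 0 (546 unadjusted) for dose. S. pombe had 452 for dose. List adjusted p was 0.109 for cell wall. Under median centring, S. cerevisiae had 686 for time, 1088 for mean KCl, 1283 for 0.8 M against 0.2 M at 10 min and 2280 for any point. N. glabratus had 811 for time, 408 for mean KCl and 1 for dose. K. lactis had 2332 for 0.8 M against 0.2 M at 10 min. C. albicans had 0 (504 unadjusted) for dose. S. pombe had 1979 for time and 707 for dose. The direction turned for the lists of cell wall (adjusted p = 0.342), tricarboxylic acid cycle and respiration (adjusted p = 0.771) and glycolysis and fermentation (adjusted p = 0.0112). List adjusted p was 0.911 for proteasome. With the deposited value table, S. cerevisiae had 8 for mean KCl. N. glabratus had 0 (1846 unadjusted) for dose. C. albicans had 0 (607 unadjusted) for dose and 63 for time. In S. cerevisiae at 10 min 0.8 M against 0.2 M split into 741 higher and 709 lower with the processed log ratios and 1139 and 144 under median centring, against 163 and 25 after loess. In K. lactis it split into 1503 and 829 under median centring, against 223 and 210.

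With each series' own T0 as a block, S. cerevisiae had 0 (1675 unadjusted) for time. N. glabratus had 325 for time, 182 for mean KCl and 0 (1054 unadjusted) for dose. C. albicans had 6 for time, 23 for mean KCl and 0 (356 unadjusted) for dose. S. pombe had 75 for time and 379 for mean KCl. List adjusted p was 0.0741 for cell wall. With the slide as a block and repeat arrays separate, S. cerevisiae had 0 (1296 unadjusted) for time. N. glabratus had 1937 for time, 1265 for mean KCl, 644 for dose and 1092 for 0.8 M against 0.2 M at 10 min. K. lactis had 3627 for any point. C. albicans had 405 for time, 166 for mean KCl and 3364 for any point. Within slide 1 alone, the count for time was 447 in N. glabratus and 1 in K. lactis. Within slide 2 alone, the count for time was 0 (200 unadjusted) in N. glabratus, 1848 in N. castellii, 0 (204 unadjusted) in C. albicans and 0 (120 unadjusted) in S. pombe. With repeat arrays kept separate, N. glabratus had 6 for dose. N. castellii had 4220 for dose, 2616 for time, 1175 for mean KCl, 3697 for 0.8 M against 0.2 M at 10 min and 5375 for any point. K. lactis had 1 for time, 1255 for 0.8 M against 0.2 M at 10 min and 3758 for any point. C. albicans had 2 for dose, 607 for time, 146 for mean KCl, 1653 for 0.8 M against 0.2 M at 10 min and 3599 for any point. S. pombe had 175 for dose and 1782 for time.

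Without the intensity trend, S. cerevisiae had 119 for 0.8 M against 0.2 M at 10 min. N. glabratus had 0 (1845 unadjusted) for dose. K. lactis had 191 for 0.8 M against 0.2 M at 10 min. Without the arrays whose labels disagree, S. cerevisiae had 1062 for time, 2092 for mean KCl and 683 for dose. With time alone and no dose slopes, S. cerevisiae had 4 for time. N. glabratus had 41 for time and 13 for mean KCl. C. albicans had 15 for time and 12 for mean KCl. S. pombe had 20 for time and 0 (1412 unadjusted) for mean KCl. On a linear dose scale, the count for dose was 818 in S. cerevisiae, 1713 in N. glabratus, 5 in C. albicans and 1173 in S. pombe. Without the 0.8 M samples after T0, S. cerevisiae had 3636 for time and 1061 for mean KCl. N. glabratus had 2479 for time and 1214 for mean KCl. N. castellii had 2838 for time and 2239 for mean KCl. K. lactis had 1282 for time and 674 for mean KCl. C. albicans had 1487 for time and 379 for mean KCl. S. pombe had 2324 for time. With each point on its own and the spread from T0 alone, the F test over all dose and time points was set beside the time test, which has another form. It called 854 genes in S. cerevisiae, 2623 in N. glabratus, 3069 in N. castellii, 2186 in K. lactis, 2223 in C. albicans and 2769 in S. pombe.

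With an estimated correlation in camera, list adjusted p was 0.329 for glycerol metabolism and transport, general stress response, cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerase I and III subunits, amino acid biosynthesis, cell cycle cyclins and core histones, phosphate starvation response, glycolysis and fermentation, 0.389 for trehalose and glycogen metabolism, 0.414 for cell wall, ergosterol biosynthesis, 0.424 for tricarboxylic acid cycle and respiration, proteasome and 0.0753 for general stress response (S. pombe). With fry, list adjusted p was 0.0685 for glycerol metabolism and transport, 0.0892 for trehalose and glycogen metabolism, 0.0224 for mating and filamentous growth MAPK targets, 0.161 for cell wall, 0.0767 for ergosterol biosynthesis, 0.213 for tricarboxylic acid cycle and respiration and 0.19 for proteasome. Without the filter on dim probes, N. glabratus had 0 (1876 unadjusted) for dose. List adjusted p was 0.0435 for cation transport and homeostasis. With probes well above background in both channels on every array, list adjusted p was 0.0322 for cation transport and homeostasis.

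In N. castellii the slide parts the repeat arrays 1 and 2 at 0.8 M, so a slide block is also a replicate block there. With it, N. castellii had 1524 for time, 2121 for mean KCl, 3699 for dose, 3417 for 0.8 M against 0.2 M at 10 min and 5389 for any point. In the 0.8 M series alone, 4758 genes changed without and 4841 with the number as replicate block, and 4730 in both. Differences between arrays 1 and 2 correlated between times at 0.362, 0.165, 0.187, 0.0990, 0.00947 and 0.0388, all positive but over 0.1 in 3 of 6, so the numbers were not taken to pair the samples, although arrays of 1 number lay on 1 slide. Other settings gave 4461 to 4758 genes in that series, and leaving out 1 array gave 4353 to 4772.

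Each T0 sample and KCl point was also left out in turn, and for the point-by-point fit each T0 sample. In N. castellii the 15 fits gave 0 genes for time, mean KCl and dose, with 132 to 1830 unadjusted. Counts for time ran from 0 (in 10 of 14 fits, with 1243 to 1691 unadjusted) to 1602 (without 0.8 M 40 min) in S. cerevisiae, from 348 (without 0.4 M T0) to 2031 (without 0.2 M 40 min) in N. glabratus, from 0 (in 13 of 15 fits, with 139 to 492 unadjusted) to 262 (without 0.8 M 20 min) in K. lactis, from 5 (without 0.4 M T0) to 398 (without 0.2 M 20 min) in C. albicans and from 54 (without 0.4 M T0) to 1671 (without 0.8 M 40 min) in S. pombe. Counts for mean KCl ran from 0 (in 9 of 14 fits, with 820 to 1879 unadjusted) to 1652 (without 0.4 M 40 min) in S. cerevisiae, from 4 (without 0.4 M T0) to 1502 (without 0.4 M 40 min) in N. glabratus, from 0 (in 12 of 15 fits, with 217 to 1060 unadjusted) to 507 (without 0.8 M 20 min) in K. lactis, from 1 (without 0.4 M T0) to 224 (without 0.2 M 20 min) in C. albicans and from 14 (without 0.4 M T0) to 1818 (without 0.2 M 40 min) in S. pombe. Counts for dose ran from 0 (in 12 of 14 fits, with 495 to 1433 unadjusted) to 717 (without 0.2 M 40 min) in S. cerevisiae, from 0 (in 9 of 15 fits, with 1094 to 1772 unadjusted) to 1420 (without 0.2 M 40 min) in N. glabratus, from 0 (in 14 of 15 fits, with 92 to 760 unadjusted) to 94 (without 0.2 M 20 min) in K. lactis, from 0 (in 11 of 15 fits, with 405 to 1308 unadjusted) to 1 (in the other 4) in C. albicans and from 0 (in 6 of 15 fits, with 1237 to 1441 unadjusted) to 964 (without 0.2 M 40 min) in S. pombe. Genes for 0.8 M against 0.2 M at 10 min ran from 0 (without 0.8 M T0, with 1038 unadjusted) to 582 (without 0.2 M T0) in S. cerevisiae, from 494 (without 0.4 M T0) to 2250 (without 0.2 M T0) in N. glabratus, from 17 (without 0.4 M T0) to 1002 (without 0.8 M T0) in K. lactis and from 659 (without 0.4 M T0) to 1450 (without 0.8 M T0) in S. pombe. Genes for any point ran from 122 (without 0.8 M T0) to 1729 (without 0.2 M T0) in S. cerevisiae, from 445 (without 0.4 M T0) to 3454 (without 0.2 M T0) in N. glabratus, from 490 (without 0.4 M T0) to 2962 (without 0.8 M T0) in K. lactis and from 1641 (without 0.4 M T0) to 3053 (without 0.8 M T0) in S. pombe. List adjusted p ran from 0.0335 (without 0.4 M 40 min) to 0.0602 (without 0.4 M 80 min) for cation transport and homeostasis and from 0.00252 (without 0.4 M 20 min) to 0.201 (without 0.4 M 40 min) for cell wall.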

Other observations

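All tests in this part come from the point-by-point fit, which was chosen after the data were seen, and values are log2 changes against T0 with the standard error and limma's adjusted p where it is given.

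At 0.8 M and 80 min 98 genes of S. cerevisiae passed, 5 of them general stress genes. SED1 and CWP1, which encode cell wall mannoproteins, stood 3.23 ± 0.19 (adjusted p = 0.020) and 3.57 ± 0.39 (0.040) above T0, against 2.80 and 4.40 at 40 min. The secreted acid phosphatase gene PHO5 fell by 3.33 ± 0.19 (0.020) and SPL2, a regulator of phosphate uptake, fell by 2.87 ± 0.25, within 8 of 16 phosphate genes down, where 14 fell at 40 min. Ergosterol synthesis genes fell in 6 of 27 cases (9 down and 4 up at 40 min), with ERG2 at -1.63 and the azole target ERG11 at -1.11. The histone H2A gene HTA1 fell by 1.80 ± 0.11 at that point. Without the T0 sample of the 0.8 M series 3 genes, in place of 98, passed at this point.

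At 0.8 M and 40 min the G1 cyclin gene CLN2 fell by 1.84 ± 0.12 and the mitotic cyclin gene CLB2 by 2.15 ± 0.24. Amino acid synthesis genes fell in 30 of 64 cases and rose in 3, with ASN1, an asparagine synthetase gene, down by 2.06 ± 0.18. FAR1, which encodes a cyclin-dependent kinase inhibitor of the mating pathway, fell by 2.67 ± 0.32 and the pheromone receptor gene STE2 fell by 1.95, within 7 down and 4 up of 19 genes of the mating list (median -0.12). Among the osmosensing genes the stress transcription factor gene MSN2 rose by 1.87 ± 0.28 and the sensor gene SHO1 fell by 1.02 ± 0.14, within 11 up and 5 down of 24. RPN4, the transcription factor gene of the proteasome, rose by 1.70 ± 0.28, and the citrate synthase gene CIT1 rose by 2.15 ± 0.42, although the median of the respiration list there was 0.29 after loess and -0.01 under median centring. Every S. cerevisiae gene named here passed limma at its point and kept its sign under median centring and with the processed log ratios.

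The N. castellii array whose title adds Pi to 0.4 M and 20 min was in no comparison. It differed from the 0.4 M 20 min sample by over 2-fold in 3 of 5527 genes, 1 higher and 2 lower, with an RMS log2 difference of 0.112, and its changes against T0 correlated with those of that sample at r = 0.992 across genes. Repeat arrays of N. castellii differed by over 2-fold in 0 to 21 genes.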
